A study of Homo sapiens with 5 samples.

How the data were processed

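Gene expression was measured in human mast cells derived from peripheral blood, with 1 array for each of 5 conditions. Per the labels, cells were loaded with IgE at 1 ug/ml for 48 h, incubated for 1 h with DEX at 1 uM, FK506 at 0.1 uM or DMSO at 0.01%, and stimulated with anti-IgE for 6 h, except in the condition of DMSO alone. The sample descriptions give anti-IgE as 1.5 ug/ml, while another label of the vehicle sample gives 15 ug/ml; the labels do not settle which holds. Per the labels, biotin-labelled cRNA made from 5 ug of total RNA was hybridized to the U133 Plus 2.0 array. No source used here says whether the arrays shared a cell preparation or a hybridization day.

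The authors deposited 1 table of probe-set signals, which are array intensity values on a linear scale, for 54675 probe sets. The software, the summary of probes into probe sets, the background correction and any scaling are not given in the sources used here, so the scale factor of the deposited values stays unknown. The deposited values are never negative and were not centred per probe set. The deposited intensity medians were 101, 80.3, 74.0, 72.9 and 82.6 for DMSO alone, vehicle, DEX, FK506 and both drugs, and the upper quartiles were 443, 342, 317, 312 and 309. Hybridization spikes, RNAs added to each sample in fixed amounts, had geometric means of 1975, 1741, 1592, 1662 and 1389.6 in the same order. Spearman correlations across probe sets ran from 0.941 to 0.964, highest between the vehicle and DEX arrays; probe sets are not independent replicates.

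The following choices were made before the data were examined: the 7 comparisons, the rule for scaling, the floor, the fold thresholds, the 25 gene lists, the rule for named genes and the alternatives, apart from those stated here as added later. The highest array median was 1.39 times the lowest, above the preset limit of 1.1, so the 5 arrays were quantile-normalized. The median of all normalized values, 82.1, served as the floor, and lower values were set to it. Gene names came from the platform annotation, updated through Entrez identifiers: 42898 probe sets were listed, 41097 with 1 gene and 1801 with several, and 11777 were not listed. Of those with 1 gene, 41043 matched a current Entrez record. Each of 19738 genes was represented by its probe set with the highest mean signal, and for 10509 genes another probe set could be compared. On all arrays 6566 genes lay under the floor. Probe sets with several genes were not used, which left 3 of the 20 genes fixed for naming without a value. XIST and Y-linked genes were left out of every table.

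Each comparison set 1 array against 1 array on the log2 scale, with no test. A gene counted as higher or lower at 2-fold with its higher value above the floor, and as induced at 4-fold. The share of induction left was 100 times the drug value minus DMSO alone over the vehicle value minus DMSO alone, on linear signals, with a 95% interval of the median from order statistics over genes, which leaves out array error. The named genes were, per drug or stimulus comparison, the 6 largest changes each way above the floor on both arrays, the 4 largest lower bounds each way, and up to 4 changed members per list; 20 genes were named wherever measured, and between drugs the 5 largest each way. The lists hold 612 gene entries, 548 of them measured, and their names and results are given with the comparisons. A list median was set against 10000 random lists of the same size matched on mean signal, which describes these arrays and is no test of the conditions. The random lists were not matched on the change with anti-IgE, which matters for drug comparisons of lists that rose on the vehicle array. The plan named the median of each list without a filter on its members. Restricting it to members above the floor on at least 1 array was decided after seeing the data, and medians over all members are given as an alternative.

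Array noise was modelled as Gaussian, with an SD taken from the median absolute difference of the closest pair of arrays at each signal level: 0.29 log2 units at a signal of 100, 0.17 at 500, 0.14 at 2000 and 0.087 at 10000. This model takes the DEX array for a repeat of the vehicle array and leaves out heavy tails and differences between cell preparations. It was used in 1000 simulations of unchanged drugs. The calling step was tested on simulated data for anti-IgE against DMSO alone over 19738 genes, with 25 genes changed at each fold. All changed genes had a mean signal above 4 times the floor, so recovery of dimmer genes was not tested. The step recovered 100% of genes raised or lowered 8-fold, and 96% raised and 100% lowered 4-fold. At 3-fold it recovered 96% raised and 100% lowered. At 2-fold, the threshold itself, it recovered 48% raised and 36% lowered, and it called 12 unchanged genes.

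The alternatives were the values as deposited, scaling by the 75th percentile, a floor at the 25th percentile (20.6), no floor, a pseudocount of 82.1 in place of the floor, the median over the probe sets of a gene, a 3-fold threshold, induction at 3-fold or 8-fold, and the share of induction left on the second brightest probe set. Added after seeing the data were the look-up of drug calls in a contrast sharing no array, of anti-IgE calls on all 4 stimulated arrays and of calls on the second brightest probe set. The comparison of restricted list medians with those over all members was also added then, since the restriction was. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Probe-level scanner data and any other assay of these cells were not analysed here.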

Results

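Messenger RNA levels were measured in human mast cells derived from peripheral blood, on 5 Affymetrix U133 Plus 2.0 oligonucleotide arrays. Mast cells are tissue-resident immune cells that hold IgE on a high-affinity receptor and release mediators when that IgE is cross-linked. The cells had been loaded with IgE, and an antibody to IgE then cross-linked the receptors for 6 h. Each array held a different condition: DMSO alone, anti-IgE after the vehicle DMSO, anti-IgE after dexamethasone (DEX, a synthetic glucocorticoid), anti-IgE after FK506 (tacrolimus, an inhibitor of the phosphatase calcineurin), and anti-IgE after both drugs. The series asks how these drugs act on chemokine induction. With 1 array per condition there were no replicates, so no difference given here has a replicate check, no p-value is given, and the number of arrays limits the precision.

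The deposited signals had medians of 101 in DMSO alone, 80.3 with anti-IgE and vehicle, 74.0 with DEX, 72.9 with FK506 and 82.6 with both drugs. They were quantile-normalized, and normalized signals below a floor of 82.1 were set to that floor. A gene was said to rise or fall at a difference of at least 2-fold with its higher signal above the floor. Where the lower signal was under the floor, the fold is a lower bound, given as "at least". Simulated array noise, without heavy tails or differences between cell preparations, gave a median of 5 genes higher and 5 lower between equal arrays. These counts are not an estimate of false calls. The 3'/5' signal ratios ran from 1.02 to 1.11 for ACTB and from 0.792 to 0.857 for GAPDH. Bacterial control probe sets, which have no target in the cells, had median signals of 4.6 to 7.4.

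The first comparison, anti-IgE with vehicle against DMSO alone, asked what receptor cross-linking changed. The labels give no further time in culture for DMSO alone, so a difference in culture time cannot be told apart from cross-linking. CXCL8, which encodes the neutrophil attractant interleukin-8, rose 109-fold, from a signal of 109 to 11874. CCL4 rose 94.6-fold to 12621, and CCL1, the ligand of CCR8, rose at least 103-fold to 8477. CXCL3, also a neutrophil attractant, rose at least 12.7-fold, and the monocyte attractant CCL7 rose at least 8.58-fold. CCL2, another monocyte attractant, already stood at 4222 in DMSO alone and rose 2.75-fold, and CCL18 rose 3.66-fold. Of the 16 listed chemokines above the floor, 8 rose and 0 fell, with a median log2 difference of 0.86 at percentile 100 of random lists matched on signal. That median was 0.00 when members under the floor on every array were included, and 1.41 with the signals as deposited. CCL8 and CCL20 lay under the floor on all 5 arrays and have no fold.

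**Figure D1:**
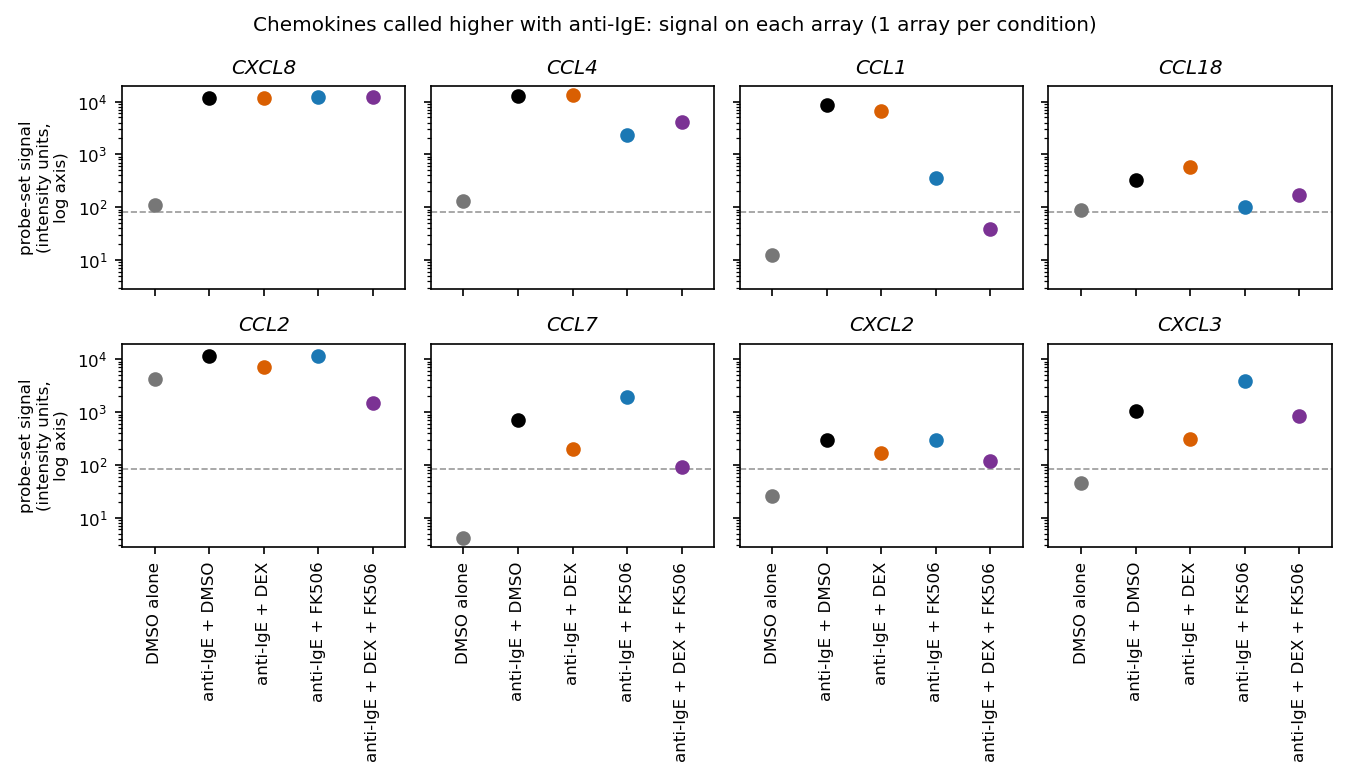
Probe-set signal in intensity units on a log axis for the 8 chemokines that rose with anti-IgE, with 1 point per array and a dashed line at the floor of 82.1. The CXCL8 probe set shown lies between 11874 and 12462 on all 4 stimulated arrays, although the other CXCL8 probe set, not shown, goes from 12578 with vehicle to 8637 with DEX and 7026 with both drugs, and CCL1 goes from 8477 with vehicle to 354 with FK506 and to below the floor with both drugs.

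Cytokine and growth factor genes also rose with anti-IgE, 9 of the 24 above the floor, and 1 fell. INHBA, which encodes a subunit of activin A, rose at least 61.7-fold, and IL3, a growth factor of basophils and mast cells, rose at least 33.6-fold to 2758. CSF1, the macrophage growth factor, rose 9.64-fold, HBEGF at least 5.32-fold and IL5 at least 3.72-fold. TNF rose at least 2.14-fold to 176, while IL13 had signals of 97.4 and 124 and did not pass. The list had a median of 0.65, and 0.11 when members under the floor on every array were included. In the TNF and costimulatory family, 7 of 22 rose and 0 fell, among them the costimulatory receptor TNFRSF9 (33.8-fold), the OX40 ligand TNFSF4 (9.22-fold) and CD83 (7.37-fold), with a list median of 0.66.

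NF-kappaB feedback genes had a list median of 1.22, with 12 of 21 members higher and 1 lower. It was the highest of the 25 lists after quantile normalization, while the chemokine list stood above it as deposited (1.41 against 0.93) and with 75th percentile scaling (1.64 against 1.31). BCL2A1, which encodes a survival protein, rose 16.9-fold, the adaptor TRAF1 10.5-fold, NINJ1 7.11-fold and the superoxide dismutase SOD2 5.36-fold. Apoptosis regulators rose in 6 of 18 cases and fell in 0, with a median of 0.74, led by BCL2A1, GADD45B (6.40-fold) and the caspase-8 regulator CFLAR (4.09-fold). The calcineurin-NFAT and nuclear receptor 4A list, of genes downstream of calcium signalling, had 7 members higher and 2 lower among 18 and a median of 0.40, which came to 0.06 as deposited. NR4A3 rose at least 7.75-fold, NR4A2 7.66-fold, RGS1 5.67-fold and RCAN1 4.57-fold. In the unfolded protein and amino acid stress list 4 of 22 members rose and 0 fell, with a median of 0.39, or 0.19 as deposited. The 4 were SDF2L1 (2.75-fold), PDIA4 (2.68-fold), SLC7A11 and HSP90B1. Among AP-1 and MAPK feedback genes 7 rose, such as the phosphatase DUSP5 at 10.3-fold, and 1 fell. Their median was 0.07 after normalization and -0.03 as deposited. Outside the lists, FGL2 rose 35.8-fold, the small GTPase gene GEM at least 51.7-fold, the actin-binding XIRP1 at least 117-fold and SOWAHC 17.4-fold. The tyrosine phosphatase PTPRE rose 17.4-fold on its brightest probe set, the next being under the floor.

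Genes that fell with anti-IgE included signalling components of the receptor itself. In the Fc epsilon RI list 6 of 25 members fell and 1, the kinase FYN, rose, with a median of -0.36 at percentile 0.22. The inositol phosphatase INPP5D fell 3.52-fold, the kinases SYK and BTK 3.0-fold and 2.87-fold, and the adaptor LAT2 2.93-fold. Interferon-stimulated genes had a median of -0.57 at percentile 0, with 4 of 22 lower and 0 higher, among them IFIT1 (4.42-fold) and XAF1 (3.51-fold). Of 30 mast cell identity genes 5 fell and 1 rose, with a median of -0.24 that came to -0.01 with 75th percentile scaling. SLC45A3 fell 8.96-fold, the inhibitory receptor SIGLEC8 5.16-fold and the vesicular monoamine transporter SLC18A2 2.43-fold. Among enzymes of prostanoid and leukotriene synthesis 2 of 17 fell and 0 rose, ALOX5 by 3.63-fold and the thromboxane synthase TBXAS1 by 2.61-fold, with a median of -0.30 that came to -0.10 with 75th percentile scaling. Another TBXAS1 probe set went from 584 to 423, short of 2-fold. PTGS2, the inducible cyclooxygenase, had signals of 3751 and 6649 and did not pass. The heparan sulfate sulfotransferase HS3ST1 fell 15.7-fold, TOX2 12.1-fold, the GMP reductase GMPR 11.2-fold, AGTRAP 9.47-fold and SAMD14 9.01-fold. The endothelin receptor EDNRB fell at least 8.16-fold and the exchange factor RASGRP2 at least 7.61-fold. DEPTOR, an inhibitor of mTOR, fell at least 8.70-fold on its brightest probe set, the next being under the floor and so without a fold.

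Markers of other blood cell types gave few calls with anti-IgE. The 6 monocyte and macrophage markers above the floor had a median of -0.16 at percentile 21.0, or -0.51 as deposited and 0.00 with all members, and CD14, the lipopolysaccharide co-receptor, was the one that fell, by at least 6.81-fold. The lymphocyte list had a median of 0.16 after normalization and -0.01 as deposited, with IL7R, a receptor chain for interleukin-7 and TSLP, 12.1-fold higher. The dendritic cell list had 0.17, and -0.15 as deposited, with 0 members past the threshold. Medians were -0.28 for erythroid and megakaryocyte markers, -0.03 for eosinophil and basophil markers, where SIGLEC8 fell, and 0.00 for neutrophil and precursor markers. Medians of reference, ribosomal and glycolysis genes were 0.02, -0.04 and 0.02, with 75th percentile scaling 0.28, 0.22 and 0.19, and as deposited -0.10, -0.16 and -0.18. The heat shock list had -0.01, or 0.20 with that scaling, with the co-chaperone BAG3 2.18-fold higher. The cholesterol synthesis list had -0.08 with DHCR7 and STARD4 higher, and the cell cycle list had -0.18 with the thymidylate synthase TYMS 2.62-fold lower.

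In all, 657 genes rose and 659 fell among 12331 above the floor on either array, 145 and 84 of them by at least 4-fold. Without normalization the split was 414 against 1458, and the median of all genes moved to -0.32. While the chemokine median rose to 1.41, other list medians went down, to 0.41 for cytokines and for the costimulatory family, 0.43 for apoptosis regulators, -0.61 for the Fc epsilon RI list, -0.86 for interferon-stimulated genes, -0.39 for cholesterol synthesis, -0.51 for the cell cycle, -0.61 for erythroid and -0.21 for eosinophil markers. Of the genes that rose, 522 were higher than DMSO alone on all 4 stimulated arrays, 187 of them by at least 2-fold on each, and 608 of those that fell were lower on all 4, 235 of them by at least 2-fold. These contrasts share the DMSO array, whose noise alone would make them go the same way, and no share for other genes is given. The second brightest probe set of the same gene was counted where it lay above the floor on either array. It went the same way for 360 of 375 genes that rose and for 340 of 356 that fell. Both probe sets of a gene read the same samples, and no share for other genes is given.

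DEX was compared with vehicle under anti-IgE to find what the glucocorticoid changed in stimulated cells. TSC22D3, which encodes the glucocorticoid-induced leucine zipper protein GILZ, rose 15.4-fold, and FKBP5, a co-chaperone of the glucocorticoid receptor, rose 11.8-fold. The signalling inhibitor SOCS1 rose 8.09-fold, NHSL1 9.71-fold, ZCCHC12 6.55-fold and PRKAR2B, a regulatory subunit of protein kinase A, 5.64-fold. The transcription factor ZBTB16 rose at least 5.68-fold and PNMT, the enzyme that makes adrenaline, at least 7.53-fold. CITED1 and BCL7C were at least 3.53-fold and 3.26-fold higher. BCL7C stood at 75.5 with vehicle, against 379 in DMSO alone, 268 with DEX and 271 with FK506. With both drugs against FK506, BCL7C had a log2 difference of -0.75 and ZCCHC12, under the floor with both drugs, -0.53. The other genes named so far rose in that contrast. With DEX against vehicle, 15 of 32 glucocorticoid-induced list members above the floor rose and 1 fell, with a median of 0.90 at percentile 100. ANGPTL4 among them rose 5.09-fold. With members under the floor on every array included, which have a difference of 0, the median was 0.36. The member that fell was MAOA, a monoamine oxidase. DUSP1, a MAPK phosphatase, rose 4.39-fold on its brightest probe set, and its next gave a log2 difference of 0.58.

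Chemokines did not move together with DEX. CCL7 fell 3.50-fold, from 705 to 202, and CXCL3 fell 3.34-fold, from 1043 to 312, while the other listed chemokines did not pass. CXCL8 stood at 11909 against 11874 with vehicle and CCL4 at 13186 against 12621. A further CXCL8 probe set had a log2 difference of -0.54. CCL1 had 6689 against 8477, CCL2 7292 against 11611 and CCL18 588 against 328. A further CCL18 probe set had 636 against 303, which is past 2-fold. The chemokine median was 0.00, and -0.18 as deposited. Cytokine genes had a median of -0.58 at percentile 0, or -0.07 with all members, with 5 of 24 lower and 0 higher. IL3 fell 3.38-fold, IL5 at least 3.72-fold, and the anti-inflammatory cytokine IL10 at least 2.37-fold. HBEGF fell 3.25-fold on its brightest probe set, with a log2 difference of -0.44 on the next and of 0.10 by the median of its probe sets. TNF had 118 against 176 and did not pass.

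NF-kappaB feedback genes and apoptosis regulators had medians of -0.26 and -0.20 with DEX, at percentiles 0 and 0.02, with 0 members past the threshold in either list. Both lists had risen on the same vehicle array, at medians of 1.22 and 0.74 against DMSO alone. A vehicle sample that responded more strongly therefore cannot be told apart from an effect of DEX here. AP-1 and MAPK feedback genes had -0.12 with DEX at percentile 0.53, with DUSP1 higher and PHLDA1 2.31-fold lower. In the TNF and costimulatory family, CD83 fell 2.12-fold and the median was -0.07. RGS1, a regulator of G protein signalling, rose 4.93-fold in the calcineurin-NFAT list, whose median was 0.00. ALOX5, the leukotriene-forming lipoxygenase, rose 3.20-fold on its brightest probe set and had at least 0.49 on the next, which was under the floor with vehicle. RCAN1 and PTGS2 had log2 differences of -0.01 and -0.10. The thrombin receptor gene F2RL2 fell 3.87-fold, COXFA4L3 3.65-fold and the basement membrane gene NID2 3.64-fold, and SLC16A14, PMCH and ROR1-AS1 fell at least 3.44-fold, 3.10-fold and 2.94-fold. PRF1, which encodes perforin, rose 2.30-fold in the lymphocyte list, whose median was -0.15. The monocyte median was 0.05 with 0 members past the threshold, and -0.03 as deposited.

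With DEX, 134 genes rose and 75 fell among 12259, 15 and 0 of them by at least 4-fold, and without normalization the split was 105 against 116 and the median of all genes -0.10. List medians as deposited were -0.38 for NF-kappaB feedback, -0.32 for apoptosis regulators, -0.24 for AP-1 and MAPK feedback, -0.16 for the costimulatory family and -0.26 for lymphocyte markers. The contrast of both drugs against FK506 shares no array with this one. There, 119 of the 134 genes that rose went the same way, 68 by at least 2-fold, as did 53 of the 75 that fell, 31 by at least 2-fold. At least 2-fold the other way went 2 of those that rose and 0 of those that fell. Genes under the floor with FK506 and with both drugs, such as IL3, IL5 and TAC1, have a difference of 0 there and go neither way. For other genes the shares going up and down were 50.6% and 45.6%.

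FK506, a calcineurin inhibitor, was compared with vehicle in the same way, and it lowered some of the most induced genes and raised others. IL3 fell at least 33.6-fold, from 2758 to a signal under the floor, and IL5 and TNF fell at least 3.72-fold and 2.14-fold to below it. CCL1 fell 23.9-fold, from 8477 to 354, CCL4 fell 5.49-fold to 2299, and CCL18 fell 3.24-fold. In the other direction CXCL3 rose 3.69-fold to 3844 and CCL7 rose 2.73-fold to 1926. CXCL8 and CCL2 had signals of 12123 and 11715, log2 differences of 0.03 and 0.01. Of 16 chemokines 2 rose and 3 fell, with a median of 0.00. RCAN1, whose product inhibits calcineurin, fell 6.47-fold.

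FOSB and FOS, which encode AP-1 subunits, rose at least 29.9-fold and at least 11.3-fold from under the floor with FK506, and FOSL1 rose 3.41-fold. Of 28 AP-1 and MAPK feedback genes 8 rose and 0 fell, with a median of 0.53 at percentile 100, and 0.49 as deposited. In the calcineurin-NFAT and nuclear receptor 4A list 6 of 18 rose and 2 fell, with a median of 0.22. Those that rose included the early transcription factors EGR1 (7.10-fold) and NR4A1 (6.36-fold) and RGS1 (8.63-fold), and those that fell were RCAN1 and NR4A2. Cytokine genes went both ways, 6 up and 5 down, with a median of 0.30, or 0.04 with all members. The growth factor EREG rose at least 7.39-fold on its brightest probe set, the next, near the floor, giving -0.19, and the alarmin IL33 rose at least 5.03-fold. The interleukin-2 receptor chain IL2RA rose 3.92-fold and the checkpoint ligand CD274 3.73-fold, while TNFRSF9 fell 3.21-fold. In that costimulatory family 2 of 22 rose and 1 fell. Among markers of other blood cell types, the 6 of monocytes and macrophages had a median of 0.41 at percentile 98.9, or 0.00 with all members, and 0 of them passed the threshold. The dendritic cell marker ITGAX rose 2.45-fold on its brightest probe set, its next being under the floor, and the erythroid marker HBD 2.04-fold.

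NF-kappaB feedback genes had a median of -0.27 with FK506, with 4 of 21 lower and 0 higher, among them SOD2 (6.69-fold) and CFLAR (2.74-fold). Of 18 apoptosis regulators 4 fell and 0 rose, with a median of -0.21. BCL2, the survival gene, fell 3.92-fold on its brightest probe set, and its next, near the floor, gave 0.21. MITF, a transcription factor of the mast cell lineage, fell 5.79-fold and was the only one of 30 identity genes past the threshold. The kinase FYN fell 3.20-fold and the phosphatase PTPN6 3.29-fold in the Fc epsilon RI list. Its median was -0.15, or -0.0023 with 75th percentile scaling. FYN had risen with anti-IgE, from 2903 in DMSO alone to 8037 with vehicle, and stood at 2511 with FK506. HERPUD1 fell 2.49-fold in the unfolded protein list, which had a median of -0.16. Of the glucocorticoid-induced list, 6 rose and 2 fell with FK506, at a median of 0.21, or 0.03 with all members. Thrombomodulin (THBD) rose 11.5-fold and TSC22D3 rose 2.09-fold, while MAOA and STOM fell 6.37-fold and 4.18-fold. FKBP5 had a log2 difference of 0.29.

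Among genes outside the lists, the integrin ITGA2 rose 10.1-fold with FK506, RAPH1 11.8-fold and the retinol dehydrogenase RDH10 9.32-fold. MTHFD2L, a mitochondrial folate enzyme, rose 14.0-fold on its brightest probe set, with 0.79 on the next. CITED1 rose at least 26.0-fold, the potassium channel gene KCNG3 at least 17.6-fold, TRBV27, a T cell receptor segment, at least 25.5-fold, and the cathepsin L pseudogene CTSLP8 14.4-fold. The probe sets of the last 2 genes belong to families of similar sequences. XIRP1 fell 34.5-fold, the retroviral envelope gene ERVFRD-1 25.6-fold, RGS4 14.5-fold, LY6G6C 13.2-fold and the deubiquitinase STAMBPL1 12.3-fold. TAC1, the precursor of substance P, fell at least 16.7-fold, BMP2 at least 11.5-fold and NPTX2 at least 10.9-fold.

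In total 352 genes rose and 289 fell with FK506 among 12390, 65 and 51 of them by at least 4-fold, and without normalization the split was 282 against 382 and the median of all genes -0.10. List medians as deposited were 0.11 for the calcineurin-NFAT list, 0.19 for cytokines, 0.09 for the glucocorticoid-induced list, -0.34 for apoptosis regulators and -0.24 for the unfolded protein list, and with 75th percentile scaling -0.17 for NF-kappaB feedback and -0.10 for the unfolded protein list. In the contrast of both drugs against DEX, which shares no array with this one, 316 of the 352 went the same way, 125 by at least 2-fold, and 269 of the 289, 138 by at least 2-fold. For other genes the shares were 48.3% and 47.5%.

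Both drugs together, compared with vehicle under anti-IgE, lowered 5 of the 16 chemokines and raised 0. CCL1 fell at least 103-fold, to 39.4 and so to below the floor. CCL2 fell 7.93-fold, from 11611 to 1465, under its level of 4222 in DMSO alone. CCL7 fell 7.76-fold and CCL4 3.09-fold, and CXCL2, named here because it completes the count, also passed. CXCL8 stood at 12462, while a further CXCL8 probe set had a log2 difference of -0.84, CXCL3 stood at 835 against 1043, and CCL18 at 173 against 328. A further CCL18 probe set went from 303 with vehicle to 67.1, under the floor, and so past 2-fold. The chemokine median was -0.16 at percentile 0.50, 0.00 with all members and -0.53 as deposited. Cytokine genes had a median of -0.34, or -0.05 with all members, with 8 of 24 lower and 2 higher, among them IL3 (at least 33.6-fold lower) and CSF1 (10.8-fold lower).

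The glucocorticoid-induced list had a median of 1.00 with both drugs, or 0.31 with all members, with 16 of 32 members higher and 2 lower. TSC22D3 rose 15.8-fold, FKBP5 15.6-fold and ANGPTL4 11.8-fold, and DUSP1 rose 15.8-fold on its brightest probe set, the next giving 0.18. NF-kappaB feedback genes fell in 7 of 21 cases and rose in 1, at a median of -0.25, or -0.46 as deposited, with SOD2 5.63-fold and the plasminogen activator PLAU 3.82-fold lower. Apoptosis regulators had -0.36, or -0.61 as deposited, with BCL2 and CFLAR lower. The next BCL2 probe set lay near the floor, at 82.9 with vehicle and 72.3 with both drugs, and did not show the fall. The costimulatory family had 5 lower and 3 higher at a median of 0.00, with TNFRSF9 9.01-fold lower and IL2RA 6.07-fold higher. The calcineurin-NFAT list had 4 higher and 3 lower at 0.22, or 0.05 as deposited, with RGS1 11.1-fold and EGR1 4.85-fold higher and NR4A2 6.90-fold and RCAN1 5.42-fold lower. FOSB and FOS rose at least 13.5-fold and 10.1-fold, but the AP-1 list median of 0.17 turned to -0.0032 with the signals as deposited. MITF fell 5.55-fold. The interleukin-1 receptor gene IL1R1 rose 15.8-fold, NHSL1 17.0-fold, RAPH1 12.1-fold, CITED1 at least 56.7-fold and PNMT at least 11.5-fold. RGS4 fell 29.2-fold, ERVFRD-1 24.5-fold, SOWAHC 11.8-fold, XIRP1 11.2-fold and STAMBPL1 10.8-fold. The monocyte median was 0.01, and -0.03 as deposited, with 0 members past the threshold. Of 4 other lists of cell-type markers 1 member each rose, HBD 3.63-fold, ITGAX 3.26-fold, with its next probe set under the floor, PRF1 2.18-fold and the neutrophil precursor marker DEFA4 at least 2.08-fold. A total of 372 genes rose and 352 fell among 12482, 62 and 73 of them by at least 4-fold, and without normalization the split was 271 against 489 and the median of all genes -0.12.

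**Figure D2:**
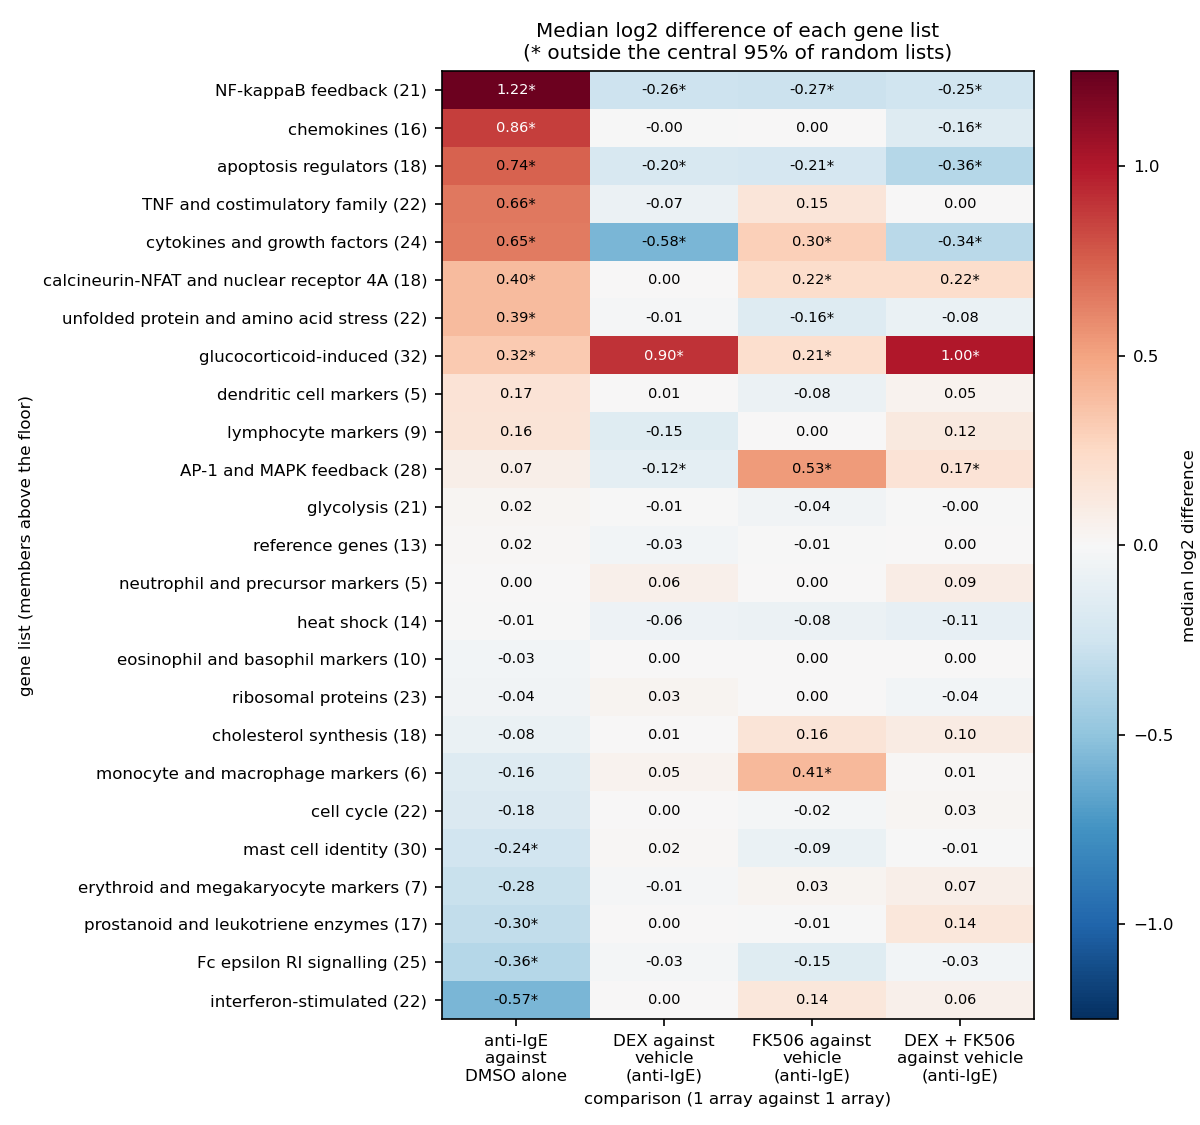
Median log2 difference of each of 25 gene lists (vertical axis, with the number of members above the floor) in 4 comparisons of 1 array against 1 array (horizontal axis), where colour and printed value give the median and an asterisk marks a value outside the central 95% of random lists. The glucocorticoid-induced list is highest with DEX (0.90) and with both drugs (1.00), and the AP-1 and MAPK feedback list is highest with FK506 (0.53), while 27 of the 100 medians, the AP-1 and MAPK feedback list with both drugs among them and each at most 0.17 from 0, change sign as deposited or with 75th percentile scaling.

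The drugs were then set side by side on the 145 genes at least 4-fold higher with anti-IgE. The median share of the induction left was 68.6% with DEX (95% interval over genes 61.8 to 75.7), 46.8% with FK506 (27.1 to 59.9) and 26.7% with both (18.2 to 48.3). As deposited the shares were 58.9%, 38.6% and 17.3%, for genes induced at least 8-fold 62.1%, 30.5% and 9.57%, with the floor at the 25th percentile 66.2%, 46.8% and 34.1%, and with no floor 61.1%, 51.2% and 44.0%, where FK506 and the combination lay closest. An unchanged drug left 97.8% in simulations that include the selection of these genes on the vehicle array. Of the 145 genes 12 were lowered at least 2-fold by DEX but not FK506, 54 by FK506 but not DEX, 15 by both drugs singly and 64 by neither. Independent effects would put 12.8 genes in the class lowered by both. Simulated unchanged drugs sharing the vehicle array put 0 there, but 1 such drug alone also lowered a median of 0. The simulation therefore cannot show what the shared array adds to the overlap. DEX raised 6 of the genes at least 2-fold, FK506 raised 18, and 36 kept under 10% of their induction with FK506 against 1 with DEX. For the 5 induced chemokines CCL1, CCL4, CCL7, CXCL3 and CXCL8 the median share left was 78.7% with DEX (19.2 to 105 from the lowest to the highest gene), 102% with FK506 (3.24 to 391) and 31.7% with both drugs (0 to 105). With FK506 the shares were 3.24% for CCL1, 17.3% for CCL4, 102% for CXCL8, 296% for CCL7 and 391% for CXCL3, so the median is that of CXCL8 alone. The other CXCL8 probe set left 68.5% with DEX, 111% with FK506 and 55.6% with both drugs, against 100.3%, 102% and 105% on the one used. The combination lay at least 2-fold below both single drugs for 17 of the 145 genes, among them CCL1, CCL7, CSF1 and TNFRSF9. Genes already at the floor with FK506 alone, such as IL3 and TAC1, could not enter this count.

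**Figure D3:**
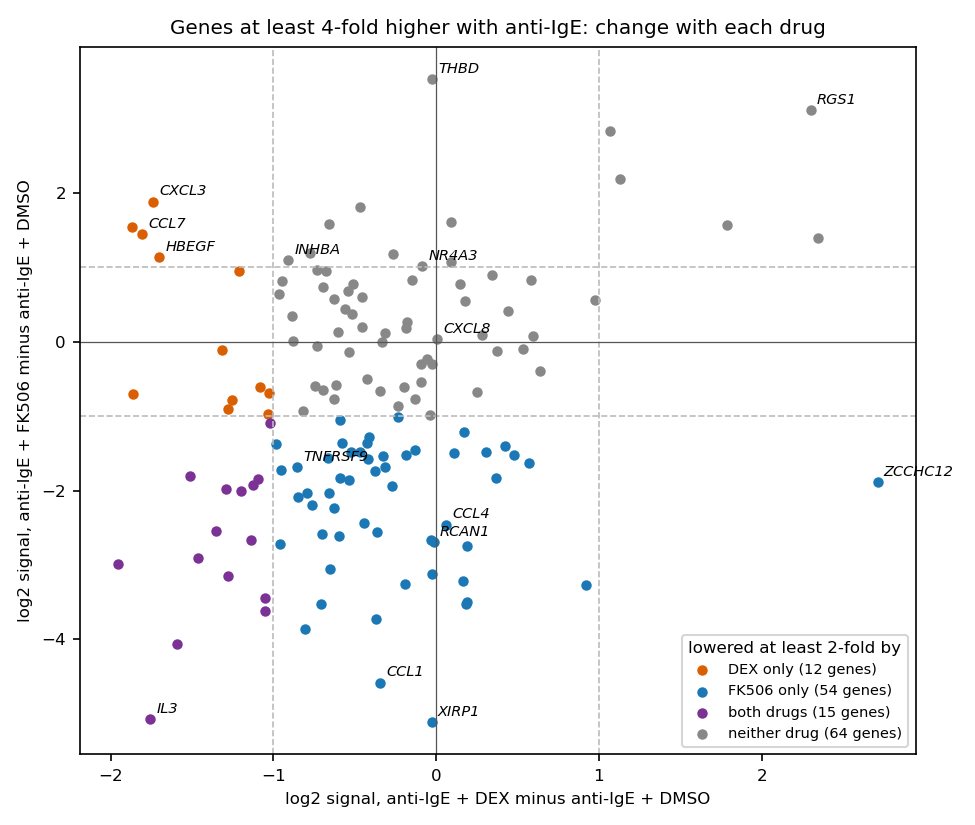
Log2 signal difference from vehicle with DEX (horizontal axis) and with FK506 (vertical axis) for the 145 genes at least 4-fold higher with anti-IgE, with 1 point per gene coloured by which drug lowered it and dashed lines at a 2-fold change. IL3 lies low on both axes, CCL1 and XIRP1 lie low on the FK506 axis, and CCL7, CXCL3 and HBEGF lie to the left with DEX and above 0 with FK506.

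Direct contrasts between drug arrays separated genes by drug. With DEX rather than FK506, XIRP1 was 33.9-fold, ZCCHC12 24.2-fold, PRKAR2B 19.7-fold, CCL1 18.9-fold and the lymphocyte co-receptor SLAMF1 18.3-fold higher. CXCL3 was 12.3-fold, the cell cycle regulator E2F7 12.1-fold, THBD 11.7-fold and the scavenger receptor OLR1 11.4-fold lower with DEX than with FK506. MTHFD2L was 23.2-fold lower, and E2F7 and MTHFD2L had -0.62 and -1.30 on their next probe sets. In total 315 genes were higher and 367 lower among 12423.

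Adding FK506 to DEX raised 187 genes and lowered 222 among 12473. CITED1 rose 16-fold, THBD 9.61-fold, VGF 6.85-fold, FOS 6.20-fold and RDH10 6.01-fold over DEX alone, and CCL1 fell at least 81.4-fold, RGS4 16.7-fold, XIRP1 11-fold, ERVFRD-1 9.98-fold, ELMO1 9.73-fold, PRKAR2B 9.07-fold and CCL2 4.98-fold. Adding DEX to FK506 raised 179 genes and lowered 206 among 12491. SLAMF1 rose 21.9-fold, NHSL1 13.5-fold, FKBP5 12.8-fold, the pentraxin PTX3 8.30-fold and the Toll pathway inhibitor IRAK3 7.62-fold over FK506 alone. CCL7 fell 21.2-fold, the oxysterol receptor GPR183 15.5-fold, MTHFD2L 10.3-fold, CCL2 8.0-fold and E2F7 7.60-fold, with -0.41 for E2F7 and -0.77 for MTHFD2L on their next probe sets.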

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

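Tests chosen only after the result was seen are the test of monocyte markers with its demand on the interval, the use of deposited medians against array brightness for FK506, and the look-up of FK506 and DEX effects in contrasts sharing no array as alternatives to the counts.

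DEX moved SLC34A3 and NIBAN3 in opposite directions with and without FK506, past 2-fold each way, which drew them out. SLC34A3, a phosphate transporter gene, had a DEX effect of 1.12 on the log2 scale with vehicle and of -1.12 with FK506, a difference of -2.23. NIBAN3, a B cell-associated gene, had 1.11 and -1.08, a difference of -2.19, with a signal of 71.6 on the vehicle array, under the floor. The second brightest probe set of each gene lay under the floor on all arrays, with highest signals of 5.16 for SLC34A3 and 24.5 for NIBAN3, so it offers no check. Neither difference was tested, since there is 1 array per condition, and no explanation was weighed.

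Probe sets without a gene name, which enter no comparison, also changed with anti-IgE. Of 11721 such probe sets that are not controls, 5047 were above the floor on some array, and 30 were at least 4-fold higher with anti-IgE than in DMSO alone, against 14 at least 4-fold lower. Of the 30, DEX lowered 2 at least 2-fold, FK506 lowered 12 and both drugs lowered 14.

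FK506 raised 352 genes over vehicle, FOSB and FOS among them. Noise of the FK506 and vehicle arrays is argued against by the contrast of both drugs against DEX, which uses neither array and gave these genes a median of 0.76, where noise alone predicted under 0.25. As to brightness, 80.1% of them stayed 2-fold higher with the values as deposited, the less favourable scaling, at the preset bound of 80%. The genes had been called after quantile normalization, which adjusts for brightness, and the median of all genes moved only to -0.10 as deposited. The share could hardly have come out low, so it shows only that most calls do not depend on the scaling. The deposited median of the FK506 array was lower than that of vehicle, by -0.14 on the log2 scale. These genes had a deposited median of 1.26, but they were selected as higher on the same arrays, so that value is no separate evidence. Noise of these arrays is thus argued against, while the scalings cannot decide on brightness. That FK506 may raise these messages in mast cells under anti-IgE is a hypothesis from the data it was found in. Differences between cell preparations were left untested, and no array held FK506 without anti-IgE.

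Anti-IgE lowered 659 genes, with signalling and identity genes among them. Noise of single probe sets is argued against for 356 of these genes by their second probe sets, at a median of -0.97. Second probe sets under the floor on both arrays were left out, and those counted read the same samples. Noise of the vehicle array is argued against by the mean of the 3 drug arrays against DMSO alone, at -1.07. As to the brighter DMSO array, 88.0% stayed 2-fold lower with 75th percentile scaling. Quantile normalization, under which the genes were called, had already adjusted for brightness, so this share could hardly have come out low. It shows only that most calls do not depend on which of these scalings was used. All of these contrasts share the DMSO array, for which there is no other, so its own noise and the time its cells spent in culture stay open. A loss of monocyte-line cells after stimulation cannot be told apart from a response of mast cells by the marker list, whose median was -0.16 over only 6 markers, -0.51 as deposited and 0.00 with all members, with CD14 at least 6.81-fold lower and an interval from -2.77 to 0.14.

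The induced genes kept a median of 68.6% of their induction with DEX. Selection of the genes on the vehicle array is argued against by simulated unchanged drugs, which left 97.8%. Noise of the selecting probe sets is argued against by the second probe sets of 90 genes, which left 66.6%. Both tests read the same vehicle and DEX samples, and the simulated noise was taken from that pair of arrays. They therefore bear on array and probe-set noise only, and cannot address a vehicle sample that had responded more strongly. A partial lowering of the anti-IgE response by DEX stays a hypothesis from the data it was found in. The share rests on 1 DEX array, and a difference between cell preparations was not tested.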

How the results depend on the processing

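The look-ups in contrasts sharing no array, on all 4 stimulated arrays and on second brightest probe sets, the restriction of list medians to members above the floor, its comparison with all members and the count of sign changes were chosen after seeing the data. No paired analysis was possible because each group has 1 array. Over all alternatives, 118 values of the main results stayed the same (counts within 1.5 times, shares within their interval) and 76 moved. Of the 700 list medians under an alternative 675 stayed within the 95% interval of the main median and 24 did not, and 1 that had lain outside the central 95% of random lists changed sign. Counted for every list median, the sign changed in 56 of the 700, from main medians at most 0.28 from 0, with 15 of 100 as deposited and 13 of 100 with 75th percentile scaling. Of the named genes' differences 1788 stayed within noise of the main value, 173 moved and 1 past the threshold turned. Scaling by the 75th percentile and the median of probe sets kept the main counts within 1.5 times, and the shares left on second probe sets lay within their intervals. Many of the genes changed, however: the median of probe sets kept 55.2% of the genes higher and 57.3% of those lower with DEX, 69.0% and 70.2% with FK506, and 69.3% and 63.6% with anti-IgE. Noise is 0.29 log2 units at a signal of 100, near the floor, and 0.087 at 10000, so calls near the floor are the least certain and genes under it have no fold. Causes of shifts were not tested beyond what a setting does by construction, namely that lower floors admit dim genes and stricter thresholds remove calls.

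Counts are given in the order anti-IgE, DEX, FK506, both drugs against vehicle, both against DEX, both against FK506 and DEX against FK506. At a 3-fold threshold 255, 35, 119, 125, 45, 48 and 115 genes were higher and 181, 12, 103, 121, 70, 51 and 136 lower. Of the induced genes 5 were then lowered by DEX alone and 3 by both drugs singly, and the combination lay below both for 4. With the floor at the 25th percentile 1227, 608, 889, 947, 735, 718 and 812 were higher and 1150, 505, 755, 831, 689, 699 and 875 lower. The classes were then 21 for DEX alone, 83 for FK506 alone, 36 for both and 117 for neither, with the combination below both for 36. With no floor 1960, 1364, 1634, 1707, 1436, 1480 and 1559 were higher and 1889, 1219, 1427, 1470, 1390, 1366 and 1596 lower. The classes were then 89, 147, 128 and 265, the combination lay below both for 82, and DEX left 61.1% of the induction.

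With a pseudocount in place of the floor, 119 genes were higher with both drugs than with DEX, 117 higher with both than with FK506, and 37 lower with DEX than with vehicle, while 7 induced genes were lowered by DEX alone and the combination lay below both drugs for 9. With the values as deposited, anti-IgE gave 414 higher and 1458 lower, DEX lowered 116, neither drug lowered 40 induced genes, and DEX and both drugs left 58.9% and 17.3% of the induction. The AP-1 and MAPK feedback median with both drugs turned from 0.17 to -0.0032 there, and the cause was not tested. With induction set at 3-fold, 23 genes were lowered by both drugs singly and 133 by neither. With induction set at 8-fold, both drugs left 9.57%. By the median of its probe sets HBEGF had a difference of 0.10 with DEX, turned from -1.70, with -0.44 on its second brightest, and the cause was not tested. Requiring 2-fold in the contrast sharing no array left 68 higher and 31 lower for DEX and 125 and 138 for FK506. Genes under the floor on both arrays of that contrast could not be kept. Requiring 2-fold on all 4 stimulated arrays left 187 higher and 235 lower for anti-IgE.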

Other observations

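The comparison of the combination with the sum of the single-drug effects, and the look-up on other probe sets, were chosen only after the values had been seen, and the genes named here, with CRISPLD2, ADORA3 and ZFP36 further on, were picked after their values were seen. For several genes the combination differed from that sum on the log2 scale. SLAMF1, which encodes a co-receptor of lymphocytes and myeloid cells, rose from 63.1 in DMSO alone to 1266 with anti-IgE, fell to 132 with FK506 and stood at 2884 with both drugs. Its combination value lay 3.53 above the sum, and 3.06 on another probe set. XIRP1 lay 1.65 above. The monocyte attractants went the other way, as CCL7 lay at -2.60 and CCL2 at -2.33 from the sum. CCL2 had signals of 7292 with DEX, 11715 with FK506 and 1465 with both drugs. RGS1 lay at -1.94, with -1.44 on another probe set, its signals being 4448 with DEX, 7787 with FK506 and 9981 with both. For the first of these probe sets the sum lies above the highest deposited signal of any array, 19576, so a value below it was bound to result. The epidermal growth factor family gene NRG1 lay at -1.91, with -1.09 on another probe set. MTHFD2L and MINDY3 lay at -2.64 and -2.08, but at -0.26 and -0.08 on their other probe sets.

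Over 10701 genes above the floor on all 4 stimulated arrays, 118 lay at least 2-fold above the sum and 131 at least 2-fold below it. Simulated noise with additive effects gave a median of 115 in either direction together, with a central 95% reaching up to 138. At 4-fold, 1 gene lay above and 5 below, against a simulated central 95% reaching up to 1 in both directions together. These differences rest on 4 single arrays, and no explanation for them was tested.

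Several genes of the glucocorticoid-induced list also changed without DEX. With anti-IgE alone 5 of the 32 rose, MAOA 6.20-fold and THBD at least 5.96-fold among them, and CRISPLD2 and ADORA3 fell. CRISPLD2 fell 4.26-fold on its brightest probe set, and its next lay under the floor on all 5 arrays. ZFP36, whose product destabilizes cytokine messages, had signals of 451 with vehicle, 1274 with DEX, 1381 with FK506 and 4034 with both drugs.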
